A study of Homo sapiens with 36 samples.

How the data were processed

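Total RNA was purified with an RNeasy Plus Mini kit and made into libraries with the Illumina TruSeq RNA kit, per the labels' protocols. Whether the kit selected polyadenylated RNA or kept strand is not given in the sources used here. Cells grew in 6-well plates and were treated a day after seeding. The submitters' processing notes name TopHat2 2.1.0, Bowtie2 2.2.6, Cufflinks 2.2.1, R 3.5 and the genome build hg19, without their roles. The program that computed the TIN is not given in the sources used here.

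Each of the 36 deposited tables holds a score for every one of 82960 UCSC transcripts, the transcript integrity number, beside the chromosome, start and end, per the file headers. The deposited score runs from 0 to 99.9, and its lowest value above 0 is 0.0098. It measures the evenness of coverage and depends on depth where coverage is thin, so a deeper library can list more transcripts above 0. Read counts and the depth of each library were not used here, and no interval that needs depth is given. A TIN of 0 is called silent in the closing parts only as a short word for that value. A transcript much shorter than 1 kb can move between 0 and over 90 with very few reads, which bears on several of the named transcripts. The table of shCTL DMSO replicate 1 writes its values with fewer digits than the others, for a reason not given in the sources used here; the library was kept, and leaving it out is among the alternatives. Coordinates are those of the tables, written from 1.

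Groups were taken from the sample titles. For the shCTL libraries the treatment characteristic gives DMSO where the title gives the combination and the reverse; the titles were kept, and the other grouping was run as an alternative. The design of the series mentions PANC-1 alone, so the T98G libraries are known from their own labels.

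Values were tested as deposited, with no scaling, with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend), in one fit per run of 12 libraries, so that all groups of a run share one estimate of the spread. A transcript uneven in some groups thus has a wide spread in pairs of the other groups too. A lost call then need not mean that the pair itself is uneven. Groups with every library at 0 add no spread, so the estimate can understate the spread of a group above 0. An SD printed beside a p-value is that of its group alone. The cell line comparison used one fit of 24 libraries. Transcripts above 0 in at least 3 libraries of the fit were kept, which left 61335 in the PANC-1 treatment run, 57584 in T98G, 58742 in the knockdown run and 62900 in the fit of both cell lines. Where a replicate number was left out, 2 libraries per group remained and the spread was again pooled over groups. P-values were adjusted by Benjamini-Hochberg over transcripts, and a call needed an adjusted p below 0.05. The R packages jsonlite 2.0.0 and data.table (version 1.17.8) were used, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Detected transcripts and the median TIN over transcripts covered in every library of a run were compared by exact two-sided permutation tests of 3 against 3 libraries, which cannot go below 0.1.

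Transcripts that overlap on a chromosome were joined into 23485 loci without regard to strand, which the tables do not hold; an antisense RNA and its partner therefore cannot be told apart by reads here, and ACTA2-AS1 lies in a locus of 25 transcripts. A locus counted as higher or lower when it held calls in that direction and none in the other. For the regional counts, loci of the main chromosomes were placed in windows of 2 Mb with at least 10 loci and tested by one-sided Fisher's exact tests, adjusted over windows and both directions within a comparison. That scan was chosen after the values had been seen. Neighbouring genes are not independent, so its p-values are likely to be too small. Overlaps of calls between runs are given with the number that independent lists would share; they count transcripts, where one per gene had been planned.

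Gene names were the main gap. The tables give UCSC identifiers with no symbols, and the reference table of gene names used here (GRCh38.p14) holds such identifiers only as synonyms of a few noncoding genes. It matched 7 identifiers, of which 6 lay on the same chromosome and were used for their names, and 1 had the same version. The gene lists fixed before the data were examined, the look-up of ATF3 and the fits with one transcript per gene could not be run for that reason, and the rule for named genes used its fallback: at most 2 identifiers that rose and 2 that fell per comparison, those with the largest changes past the threshold, one per locus, and for pairs of groups with all 3 libraries of one group above all 3 of the other. The 6 noncoding RNAs are named because their identifiers had a name; that step was added after the tables had been seen and used no value. HNF4A-AS1 was listed at 0 in all 36 libraries and ZNF350-AS1 passed no test of the fits with all libraries.

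The test was checked on simulated data made from the mean of a DMSO group and resampled residuals of each run, with 200 transcripts of mid-range TIN shifted. Changes of 5, 10 and 20 points were recovered in 11.8%, 36.4% and 63.6% of cases for E64FC65 against DMSO in PANC-1 (61335 transcripts), in 13.2%, 51.5% and 63.6% for the same pair in T98G (57584 transcripts) and in 23.5%, 28.8% and 60.6% for the combination against DMSO in shATF3 cells (58742 transcripts). False calls were 0 of 74, 3 of 88 and 4 of 79. Residuals were shuffled for each transcript on its own, which removes shifts shared by a whole library. Such shifts reached 7.04 points in E64FC65 replicate 3 of PANC-1. Far fewer transcripts were shifted than the 9809 called for E64FC65 against DMSO in PANC-1. These rates therefore do not cover errors from library shifts and need not hold for the real comparisons.

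For the 4 comparisons of effects, 100 arrangements each that keep the main effects, the real one included, were added after the results had been seen. In one kind the residuals of the model without the departure were permuted over libraries, and in the other, for the knockdown, the shRNA labels were exchanged within treatments. The TIN is bounded, so the value expected without a departure was also compared with the range from 0 to 100.

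Alternatives fixed before the data were examined were centring each library on its median, no filter, only transcripts above 0 in every library, the replicate number as a block, leaving out each replicate number in turn, the other grouping of shCTL, other limits for a detected transcript and a stricter threshold for overlaps. Alternatives chosen after seeing the data were one transcript per locus, leaving out haplotype and unplaced sequences, an arcsine square root scale, only spans of at least 1 kb, leaving out each single library, and leaving out shATF3 DMSO replicate 3 together with shCTL combination replicate 1.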

Results

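RNA was sequenced from 36 libraries of 12 groups with 3 libraries each. PANC-1, a human pancreatic cancer cell line, was treated at passage 5 with the solvent DMSO, with E64FC65, an inhibitor of protein disulfide isomerase, with panobinostat, an inhibitor of histone deacetylases, or with both drugs. T98G, a human glioblastoma cell line, also at passage 5, received the same 4 treatments in a separate run. In a further run, PANC-1 cells at passage 9 carried a short hairpin RNA against ATF3, a stress-induced transcription factor (shATF3), or a scrambled control (shCTL), and were treated with DMSO or with a drug combination. Doses and the time on drug are not given in the labels. For shCTL the treatment label and the title of each library are exchanged between DMSO and combination; groups follow the titles here. The labels also name either E64FC65 or another code, E64FC26, for the inhibitor in the combination of that run, so its inhibitor is not certain.

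The deposited values are transcript integrity numbers (TIN), one per transcript and library, for 82960 transcripts of the human hg19 build. A TIN runs from 0 to just under 100 and scores how evenly reads cover a transcript. It is not an expression level, so a higher or lower TIN below is a change in coverage of the transcript, and a transcript at 0 in all libraries of one group and above 0 in all of the other is called gained or lost. A TIN of 0 does not show that the RNA was absent. Read counts and sequencing depth were not used here. The PANC-1 libraries are described as biological triplicates, while nothing is said of the T98G replicates, so p-values there measure only the spread between those libraries, which may be technical.

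The number of transcripts with a TIN above 0 rose with panobinostat in both cell lines and fell with E64FC65 alone. In PANC-1 it was 54822 ± 88.7 in DMSO, 53398 ± 444 with E64FC65, 60979 ± 85.7 with panobinostat and 59710 ± 958 with the combination (mean ± SD, n = 3 each). In T98G the 4 means were 54694 ± 71.0, 53374 ± 609, 55997 ± 177 and 55611 ± 416 in the same order. The 3 libraries of each drug group lay apart from the 3 DMSO libraries of their run, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. In the knockdown run the number was 54449 ± 279 in shCTL DMSO, 58266 ± 1650 in shCTL combination, 55965 ± 1430 in shATF3 DMSO and 56401 ± 87.3 in shATF3 combination, and the shATF3 groups overlapped (exact permutation p = 1). Replicate 3 of shATF3 DMSO, at 54317, and replicate 1 of shCTL combination, at 56360, lay apart from the other 2 libraries of their groups.

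**Figure D1:**
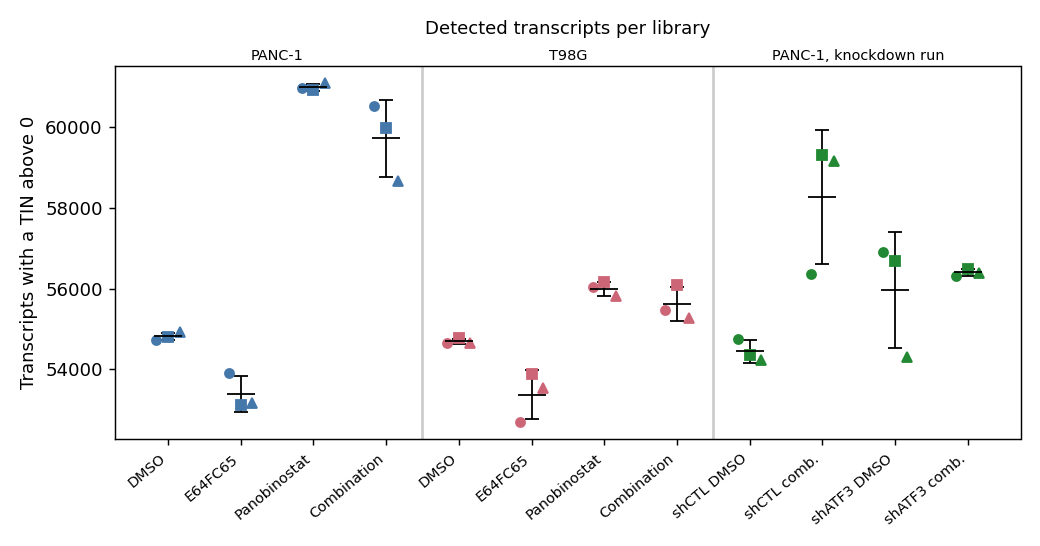
Number of transcripts with a TIN above 0 (vertical axis, not starting at 0) in each of the 36 libraries, by group. Circles, squares and triangles are replicates 1, 2 and 3, and the bar with whiskers is the mean ± SD of 3 libraries; in PANC-1 the panobinostat libraries lie between 60907 and 61074, above all DMSO libraries at 54737 to 54914.

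With panobinostat alone, PANC-1 cells had a TIN above 0 for many transcripts and loci listed at 0 in DMSO. MIR7-3HG, the long noncoding host RNA of microRNA miR-7-3 (chromosome 19, 4769117 to 4772568), was listed at 0 in all 3 DMSO libraries and had a TIN of 58.3 ± 4.86 with panobinostat (SD, n = 3; limma adjusted p = 1.25e-07). The long noncoding RNA LINC01426 (chromosome 21, 36118122 to 36157168) rose from 9.00 ± 0.254 to 20.7 ± 1.83 (n = 3, limma adjusted p = 0.000505). SLC9A3-AS1, the antisense RNA of a sodium/hydrogen exchanger gene (chromosome 5, 478318 to 480999), rose from 36.1 ± 7.30 to 69.4 ± 4.99 (n = 3, limma adjusted p = 0.00095). ACTA2-AS1 (chromosome 10, 90692441 to 90699731) stood at 26.1 ± 4.14 in DMSO and 21.5 ± 0.592 with panobinostat and passed no test. Of 61335 tested transcripts 14550 changed, 12485 with a higher and 2065 with a lower TIN. A total of 4775 transcripts went from 0 in all DMSO libraries to above 0 in all panobinostat libraries, and 99 went the other way. Of 9839 loci with all transcripts at 0 in DMSO, 1256 (12.8%) were gained.

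The share of transcripts with a higher TIN with panobinostat in PANC-1 was taken by genomic span from start to end, introns included. This is not the length of the RNA. The share was not tested, and transcripts of the same locus are not independent. Of the 10192 transcripts spanning over 100 kb, 29.9% (3044) rose, against 18.5% (6615) of those of 10 to 100 kb, 18.8% (2722) of those of 1 to 10 kb and 11.5% of those under 1 kb. The largest rises without a gene name were those of uc022cbk.1 (chromosome X, 102471082 to 102471444), at 97.8 ± 0.499, and of uc022cat.1 (chromosome X, 101408902 to 101409237), at 97.7 ± 0.229, both listed at 0 in all DMSO libraries (n = 3, limma adjusted p = 1.45e-12 and 6.45e-13). The largest falls were in the short transcripts uc001ovx.1 (chromosome 11, 74720517 to 74720547), listed at 0 with panobinostat after 93.6 ± 0.300 in DMSO (n = 3, limma adjusted p = 0.00569), and uc011czw.1 (chromosome 5, 140098511 to 140098598), at 0 after 86.4 ± 1.60 (n = 3, limma adjusted p = 0.0337). The call on uc001ovx.1 was lost without the libraries numbered 2 or 3 (adjusted p over all alternatives from 1.81e-11 to 0.0934). The call on uc011czw.1 was lost when any one of the 6 DMSO and panobinostat libraries was left out, with adjusted p from 0.082 to 0.0877, and from 0.00914 to 0.213 over all alternatives run for it. The SEs were 19.9 for uc001ovx.1 and 25.5 for uc011czw.1, although the DMSO and panobinostat libraries were even. That spread comes from the pooled fit, not from the libraries compared. With only transcripts above 0 in every library the count of changed transcripts was 6875, a setting that leaves out gained transcripts.

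E64FC65 alone lowered the TIN of far more transcripts than it raised in PANC-1, with a local exception on chromosome 6. Between 26 and 28 Mb of that chromosome, the region of the largest human histone gene cluster, 12 of 59 loci rose and 4 fell (20.3% higher, against 4.07% of all loci; one-sided Fisher's exact test, adjusted p = 0.00402 over 559 windows and both directions), a call kept in 5 of 8 other settings with adjusted p from 3.21e-05 to 1. With only transcripts above 0 in every library, 7 of 37 loci rose and 3 fell, and the call was lost (one-sided Fisher's exact test, adjusted p = 0.465). On chromosome 15, 6 of 18 loci at 84 to 86 Mb rose and 2 fell, and 6 of 20 at 82 to 84 Mb rose and none fell (adjusted p = 0.0303 and 0.0393), kept in 1 and 2 of 8 other settings (adjusted p from 0.0374 to 1 and from 0.0398 to 1). MIR7-3HG stayed at 0 in all 3 libraries, LINC01426 was at 8.90 ± 0.953 and SLC9A3-AS1 at 37.5 ± 3.67 (n = 3), and neither of the latter passed the test (limma adjusted p = 1 and 0.948). ACTA2-AS1 was at 20.6 ± 4.58 and passed only without E64FC65 replicate 1 (limma adjusted p = 0.206, 0.0469 without that library, and 0.0469 to 0.649 over all alternatives). In total 9809 transcripts changed, 1309 with a higher and 8500 with a lower TIN. The largest rises were those of uc021osz.1 (chromosome 1, 120906461 to 120906507), at 94.8 ± 0.118, and uc022cbk.1, at 94.5 ± 2.02, both from 0. TIN fell most in uc010cci.3 (chromosome 16, 56677599 to 56678853), to 0 from 79.5 ± 5.93, and uc010uuk.2 (chromosome 16, 686817 to 688620), to 0 from 79.0 ± 3.71 (n = 3, limma adjusted p = 4.51e-13, 2e-11, 2.05e-06 and 9.22e-06). Replicate 3 of E64FC65 had a median TIN of 71.0 over transcripts covered in every library, against 77.7 and 77.1 in replicates 1 and 2. With each library centred on its median, the balance moved from 13.3% to 41.3% higher, with 3235 higher and 4605 lower.

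The drug combination, the treatment named in the title of the series, gave 17979 changed transcripts against DMSO in PANC-1, 11141 higher and 6838 lower. MIR7-3HG reached 72.0 ± 5.52 from 0 in all DMSO libraries (n = 3, limma adjusted p = 2.8e-08), and LINC01426 rose to 19.6 ± 3.71 (n = 3, limma adjusted p = 0.000938). SLC9A3-AS1 was at 37.6 ± 10.5, close to its DMSO value (limma adjusted p = 0.927). In the histone cluster region of chromosome 6, 31 of 59 loci rose and 4 fell (52.5% higher, against 23.7% of all loci; one-sided Fisher's exact test, adjusted p = 0.000841), and between 42 and 44 Mb of chromosome 5, 12 of 17 loci fell and 3 rose (70.6% lower, against 16.6%; adjusted p = 0.000841). The number of gained transcripts was 3995 and of lost ones 210. Again uc022cbk.1, at 98.7 ± 0.158, and uc022cat.1, at 97.9 ± 0.854, rose most. Falls to 0 were largest in uc010uuk.2 from 79.0 ± 3.71 and uc002zti.1 (chromosome 22, 21311691 to 21318877) from 75.9 ± 5.94 (n = 3, limma adjusted p = 1.47e-12, 7.92e-13, 1.29e-06 and 3.92e-09). With only transcripts above 0 in every library 11066 changed and the balance turned, with 5009 higher and 6057 lower. The chromosome 6 call was kept in 4 of 8 other settings (adjusted p from 0.000215 to 1) and the chromosome 5 call in 4 of 8 (0.000914 to 0.529). Among transcripts above 0 in every library, 14 of 37 chromosome 6 loci rose and 4 fell, and that call was lost (one-sided Fisher's exact test, adjusted p = 0.178).

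Set against each drug alone, the combination in PANC-1 differed less from panobinostat than from E64FC65. Against panobinostat, MIR7-3HG was higher by 13.7 ± 2.85 (SE, limma adjusted p = 0.0132) and SLC9A3-AS1 fell by 31.8 ± 5.37 (SE, limma adjusted p = 0.00484). The first call was lost without the libraries numbered 1 or 2 and the second without those numbered 1 or 3, with adjusted p over all alternatives from 0.00364 to 0.277 and from 0.00314 to 0.0736. The histone cluster region again held an excess of higher loci, 13 of 59, while 9 were lower, and the median difference over its loci was 1.67 (22% higher, against 3.33%; one-sided Fisher's exact test, adjusted p = 5.83e-05). Among them were those of uc003nfr.3 (26027124 to 26027480), at 81.4 ± 3.64, and uc003njy.3 (27839623 to 27840099), at 81.2 ± 3.19, both listed at 0 in all panobinostat libraries (n = 3, limma adjusted p = 2.35e-08 and 1.76e-07). The largest falls, to 0, were those of uc002bvq.3 (chromosome 15, 100339997 to 100340056) from 92.0 ± 1.70 and uc010tqj.3 (chromosome 14, 50467796 to 50469007) from 72.3 ± 3.05 (n = 3, limma adjusted p = 2.66e-11 and 1.21e-05). In all 6911 transcripts changed, 1141 higher and 5770 lower. Centring each library on its median gave 4103, with 31.0% in place of 16.5% higher, and the count was 10903 without E64FC65 replicate 3 and 4411 without panobinostat replicate 1. The chromosome 6 call was kept in 6 of 8 other settings (adjusted p from 1.01e-06 to 1). It was lost among transcripts above 0 in every library, where 4 of 37 loci were higher and 4 lower.

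Against E64FC65 alone, most changes of the combination in PANC-1 were rises. MIR7-3HG was higher by 72.0 ± 2.85 (SE, limma adjusted p = 2.46e-08) and LINC01426 by 10.7 ± 1.72 (SE, limma adjusted p = 0.000806, lost without the libraries numbered 2, with adjusted p over all alternatives from 5.22e-05 to 0.0519). In contrast, 9 of 17 loci at 42 to 44 Mb of chromosome 5 were lower and 3 higher (52.9% lower, against 7.5%; one-sided Fisher's exact test, adjusted p = 0.00113, kept in 3 of 8 other settings with adjusted p from 0.000882 to 0.908). The largest rises, from 0, were those of uc022cat.1, to 97.9 ± 0.854, and uc022cdh.1 (chromosome X, 117959208 to 117960416), to 96.9 ± 0.0764 (n = 3, limma adjusted p = 7.92e-13 for both). The largest falls were in uc001euc.3 (chromosome 1, 150244773 to 150253335), to 0 from 76.8 ± 4.88 (n = 3, limma adjusted p = 8.67e-10), and in uc001ovx.1, to 30.6 ± 53 from 93.6 ± 0.259 (n = 3, limma adjusted p = 0.0396). The call on uc001ovx.1 was lost without any one of 11 of the 12 libraries of the run, all but combination replicate 1 (adjusted p from 0.0576 to 0.145, and from 5.73e-11 to 0.359 over all alternatives). A total of 17409 transcripts changed, 14715 higher and 2694 lower, and centring moved the share that was higher from 84.5% to 62.4% (12101 higher, 7285 lower). With only transcripts above 0 in every library the count was 10260. The histone cluster region held no excess of higher loci here, 16 of 59 (27.1%, against 30.7%; one-sided Fisher's exact test, adjusted p = 1, unadjusted p = 0.77).

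**Figure D2:**
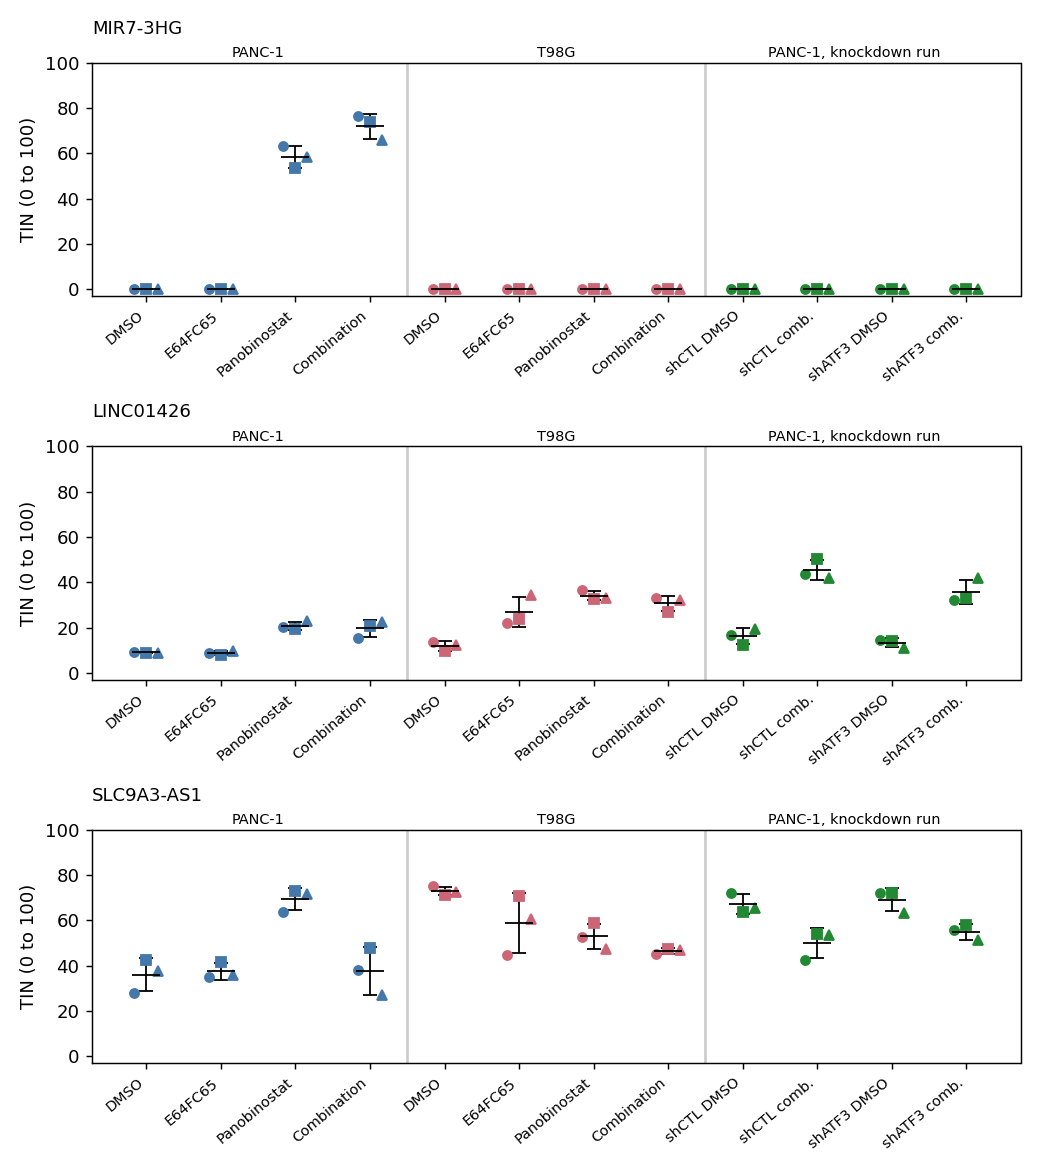
TIN (vertical axis, 0 to 100) of MIR7-3HG, LINC01426 and SLC9A3-AS1 in each of the 36 libraries, by group. Circles, squares and triangles are replicates 1, 2 and 3, and the bar with whiskers is the mean ± SD of 3 libraries; MIR7-3HG leaves 0 only in the panobinostat and combination groups of the PANC-1 treatment run.

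The test of whether the 2 drugs together departed from the sum of their single effects in PANC-1 named SLC9A3-AS1, at 36.1 ± 7.30 in DMSO, 37.5 ± 3.67 with E64FC65, 69.4 ± 4.99 with panobinostat and 37.6 ± 10.5 with both (n = 3). Its departure was -33.3 ± 7.60 (SE, limma adjusted p = 0.0308), a call lost without any one of DMSO replicate 1 or 3, E64FC65 replicate 2, combination replicate 1, or panobinostat replicate 2 or 3 (adjusted p from 0.0601 to 0.0793, and from 0.013 to 0.22 over all alternatives). MIR7-3HG departed by 13.7 ± 4.02 (SE, limma adjusted p = 0.0866) and passed the test only without combination replicate 3 (adjusted p = 0.0164, and from 0.0164 to 0.604 over all alternatives). The largest positive departures were in uc010pgs.2 (chromosome 1, 155911480 to 155912625), by 91.2, and uc003nui.4 (chromosome 6, 31543344 to 31546112), by 81.8 (limma adjusted p = 0.00386 and 0.00116). With E64FC65 alone they stood at 13.8 ± 23.9 and 8.18 ± 14.2 (SD, n = 3), uneven between libraries, and for both the sum of the single effects lies below 0, off the scale. The uc010pgs.2 call was lost without the libraries numbered 2 or 3 and the uc003nui.4 call without those numbered 1 (adjusted p over all alternatives from 5.14e-05 to 0.135 and from 0.000313 to 0.0664). The largest negative ones were -93.6 in uc022cbk.1 and -93.5 in uc021osz.1 (limma adjusted p = 3.52e-10 and 6.82e-12), transcripts that each drug alone had taken from 0 to at least 93.7, so that the sum lies above the top of the scale and a departure of about this size was fixed. The sum lay above 100 for 96 of the called transcripts and below 0 for 118 (5.43% together). Across all transcripts 3943 departed, 2533 upward and 1410 downward, and 2341 did among those above 0 in every library.

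In T98G, panobinostat alone lowered more transcripts than it raised, and LINC01426 rose while SLC9A3-AS1 fell. LINC01426 went from 11.9 ± 2.04 in DMSO to 34.0 ± 2.09 (n = 3, limma adjusted p = 0.000477), SLC9A3-AS1 from 73.0 ± 1.92 to 52.9 ± 5.64 (n = 3, limma adjusted p = 0.0248), and MIR7-3HG was listed at 0 in all 12 T98G libraries. Between 20 and 22 Mb of chromosome 19, a region of clustered zinc finger genes, 12 of 17 loci fell and none rose (70.6%, against 20.4% of all loci; one-sided Fisher's exact test, adjusted p = 0.0114 over 508 windows and both directions). Of 57584 tested transcripts 13670 changed, 5568 higher and 8102 lower, and 1422 were gained against 382 lost. Among calls of at least 10 points the balance was the other way, with 4065 higher and 3413 lower. Of 9966 loci with all transcripts at 0 in DMSO, 386 (3.87%) were gained. Rises from 0 were largest in uc001rbb.4 (chromosome 12, 13068763 to 13068852), to 94.0 ± 2.22, and uc022cei.1 (chromosome X, 133700074 to 133700712), to 90.8 ± 2.58. Falls to 0 were largest in uc001mgq.1 (chromosome 11, 8705774 to 8705903) from 89.9 ± 5.68 and uc002zuf.1 (chromosome 22, 21396681 to 21398538) from 88.9 ± 1.1 (n = 3, limma adjusted p = 1.36e-11, 1.47e-07, 4.71e-09 and 9.69e-11). Centring turned the balance, from 40.7% to 61.7% higher (8511 higher, 5294 lower), and kept the chromosome 19 call, which held in 3 of 7 other settings (adjusted p from 0.00191 to 0.421). The SLC9A3-AS1 call was lost without any one of the 3 DMSO libraries or of panobinostat replicates 1 and 3 (adjusted p from 0.0544 to 0.0894, and from 0.00203 to 0.266 over all alternatives).

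E64FC65 alone raised LINC01426 in T98G to 26.7 ± 6.57 from 11.9 ± 2.04 (n = 3, limma adjusted p = 0.00737), a call lost without the libraries numbered 2 or 3 (adjusted p over all alternatives from 0.00368 to 0.0698). SLC9A3-AS1 was at 58.7 ± 13.3 and passed the test only without E64FC65 replicate 2 (limma adjusted p = 0.111, 0.0136 without it, and 0.0136 to 0.533 over all alternatives). In the histone cluster region of chromosome 6, 23 of 52 loci had a lower TIN, which did not pass the correction over all windows (one-sided Fisher's exact test, adjusted p = 0.364). The transcripts that rose most, from 0, were uc021xjf.1 (chromosome 3, 195426272 to 195426368), to 94.5 ± 1.53 and uc004fcb.2 (chromosome X, 144329107 to 144337728), to 83.1 ± 2.92. The largest falls, to 0, were those of uc022bgf.1 (chromosome 9, 34521463 to 34521693), from 96.6 ± 3.46, and uc021ved.1 (chromosome 2, 14774104 to 14774982), from 89.1 ± 0.839 (n = 3, limma adjusted p = 6.04e-12, 2.39e-07, 9.27e-10 and 7.38e-09). In all 10498 transcripts changed, 1932 higher and 8566 lower. Centring gave 16373 and turned the balance, from 18.4% to 61.4% higher, with 10058 higher and 6315 lower.

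The combination in T98G raised LINC01426 to 30.7 ± 3.32 and lowered SLC9A3-AS1 to 46.5 ± 1.16 (n = 3, limma adjusted p = 0.000982 and 0.00436). The SLC9A3-AS1 call was lost without the libraries numbered 3 (adjusted p over all alternatives from 0.000279 to 0.0802). In the zinc finger region of chromosome 19, 13 of 17 loci fell and none rose (76.5%, against 26%; one-sided Fisher's exact test, adjusted p = 0.0194, kept in 5 of 7 other settings with adjusted p from 0.00138 to 0.14). The count of changed transcripts was 18519, with 7239 higher and 11280 lower, and 1561 transcripts were gained against 683 lost. Highest among the rises from 0 were uc001rbb.4, to 96.2 ± 0.951, and uc022azr.1 (chromosome 8, 109796410 to 109797327), to 92.2 ± 1.16. The largest falls, to 0, were those of uc001mgq.1, from 89.9 ± 5.68, and uc021uba.1 (chromosome 17, 58120386 to 58120466), from 89.8 ± 2.39 (n = 3, limma adjusted p = 9.57e-12, 3.47e-12, 4.58e-09 and 0.0272). Without any one of the 6 libraries compared, the uc021uba.1 call was lost (adjusted p from 0.0567 to 0.0692, and from 0.00767 to 0.154 over all alternatives). Its SE of 26.6 comes from the pooled fit, as the libraries compared were even. Centring turned the balance from 39.1% to 60.4% higher (12845 higher, 8439 lower).

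Compared with panobinostat alone, the combination lowered the histone cluster region in T98G: 20 of 52 loci fell and 2 rose (38.5% lower, against 9.99% of all loci; one-sided Fisher's exact test, adjusted p = 4.74e-05), which held in 5 of 7 other settings (adjusted p from 0.000149 to 0.738). Among transcripts above 0 in every library, 7 of 30 loci fell and 1 rose, and the call was lost (one-sided Fisher's exact test, adjusted p = 0.68). Against DMSO, neither panobinostat nor the combination gave a regional call there in T98G. Among the loci lower than with panobinostat, uc003nfv.3 (26045639 to 26046097) went to 0 from 85.9 ± 0.846 and uc003njw.3 (27833107 to 27833576) to 0 from 82.1 ± 6.59 (n = 3, limma adjusted p = 7.65e-06 and 0.00369). The second call was lost without the libraries numbered 1 or 3 (adjusted p over all alternatives from 1.06e-06 to 0.1). Elsewhere the largest rises, from 0, were those of uc001rfa.1 (chromosome 12, 21679256 to 21684210), to 89.0 ± 5.05, and uc021vvl.1 (chromosome 2, 207040904 to 207041971), to 87.3 ± 3.88 (n = 3, limma adjusted p = 8.34e-06 and 1.94e-08). LINC01426 and SLC9A3-AS1 did not pass (limma adjusted p = 0.561 and 0.529). In all 5600 transcripts changed, 2511 higher and 3089 lower; without combination replicate 1 the count was 9057 and the balance turned, with 5932 higher and 3125 lower. Compared with E64FC65 alone, 17134 changed, 10273 higher and 6861 lower. LINC01426 passed there only without E64FC65 replicate 3 (limma adjusted p = 0.369, 0.0282 without it, and 0.0282 to 0.942 over all alternatives). SLC9A3-AS1 passed only where E64FC65 replicate 1 was left out, alone or with all libraries numbered 1 (limma adjusted p = 0.127, 0.00416 without that library alone, and 0.00416 to 0.481 over all alternatives). The largest differences were in uc022bgf.1, at 96.5 ± 1.80 from 0, uc001rbb.4, at 96.2 ± 0.951 from 0, uc001mgq.1, to 0 from 95.2 ± 2.90, and uc021xjf.1, to 0 from 94.5 ± 1.53 (n = 3, limma adjusted p = 1.36e-10, 9.57e-12, 3.09e-09 and 3.47e-12).

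The departure from the sum of the single effects in T98G named LINC01426, by -18.2 ± 4.29 (SE, limma adjusted p = 0.026), with 26.7 ± 6.57, 34.0 ± 2.09 and 30.7 ± 3.32 under E64FC65, panobinostat and both. Without any one of DMSO replicate 2 or 3, combination replicate 2, or panobinostat replicate 1 or 3 that call was lost (adjusted p from 0.0502 to 0.0662, and from 0.0158 to 0.187 over all alternatives). The transcripts uc022bgf.1 and uc021ved.1, at 0 with E64FC65 alone, stood at 96.5 ± 1.80 and 86.1 ± 4.74 with both drugs (n = 3), and departed by 96.4 and 91.7 (limma adjusted p = 2.56e-08 and 1.5e-07). For uc021ved.1 the sum of the single effects lies below 0, off the scale. Negative departures were largest in uc021xjf.1, by -94.5, and uc010rpm.2 (chromosome 11, 66742754 to 66744479), by -70.5 (limma adjusted p = 1.66e-10 and 7.65e-05), both listed at 0 in DMSO and with the combination. Between 10 and 12 Mb of chromosome 12, 6 of 18 loci departed downward and 1 upward (33.3% downward, against 3.85%; one-sided Fisher's exact test, adjusted p = 0.0402, kept in 2 of 7 other settings with adjusted p from 0.0263 to 1). Across all transcripts 5539 departed, 4450 upward and 1089 downward, and for 73 and 536 of them the sum lay above 100 or below 0 (11% together). Centring moved the upward share from 80.3% to 54.3% (3169 upward, 2667 downward), and without combination replicate 1 the count was 9004.

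**Figure D3:**
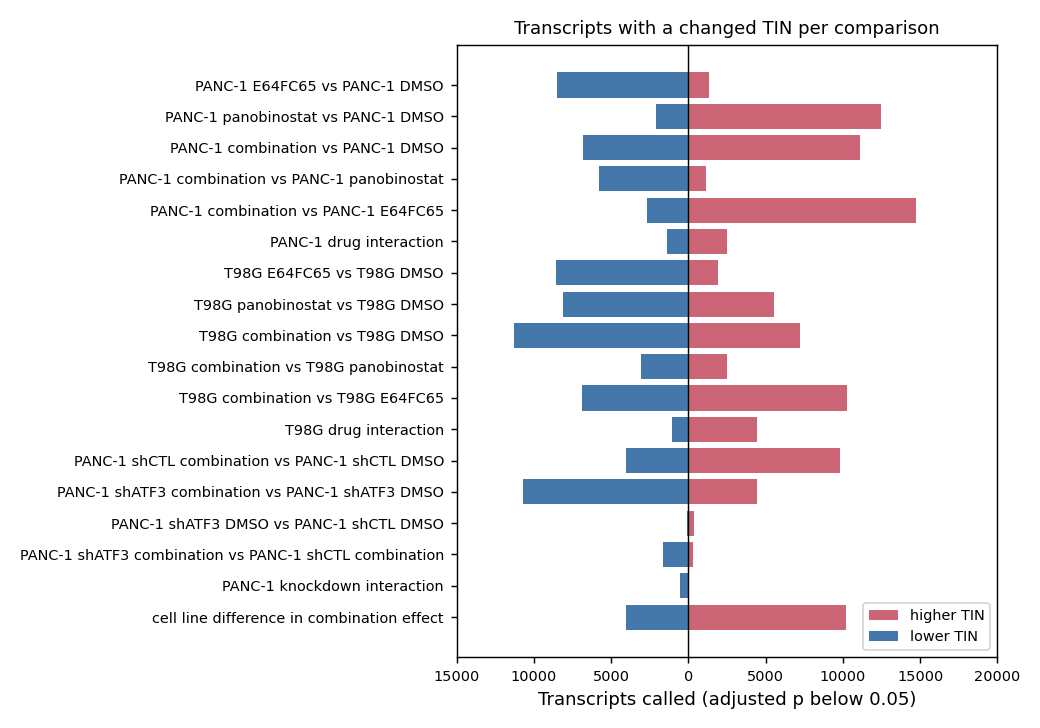
Number of transcripts with a higher (right) or lower (left) TIN at a limma adjusted p below 0.05, for each comparison of the treatment runs, of the knockdown run and of the 2 cell lines. Panobinostat raised 12485 and lowered 2065 transcripts in PANC-1, and raised 5568 and lowered 8102 in T98G.

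In the treatment runs, the 2 cell lines shared part of their response to the combination and differed in the histone cluster region. Of the transcripts tested in both, 3777 were higher in both lines, against 1087 for independent lists, and 3514 were lower in both, against 1259. Of those higher in PANC-1, 849 were lower in T98G, and of those lower in PANC-1, 165 were higher. No library is shared between the lists. Higher calls gather at a mean TIN of 0 to 25 in both lines (39.5% of that class in PANC-1 and 22.6% in T98G, against 3.25% and 6.26% at 75 to 100). The numbers for independent lists leave this out. Across those 56120 transcripts the differences correlated with Pearson's r = 0.505, where transcripts are not independent replicates. Panobinostat alone gave 3429 shared higher calls (911.3 for independent lists) and 1098 shared lower ones (263.3), and E64FC65 alone gave 324 (39.29) and 3483 (1139). Of transcripts higher in PANC-1, 844 were lower in T98G with panobinostat and 62 with E64FC65. Of those lower in PANC-1, 32 and 98 were higher. E64FC65 libraries had lower medians than DMSO in both lines, which may add to the shared lower calls. Centring moved the share that was higher with E64FC65 from 13.3% to 41.3% in PANC-1 and from 18.4% to 61.4% in T98G. The overlaps were not taken after centring. The effect of the combination differed between the lines for 14263 of 62900 transcripts, 10236 with the higher change in PANC-1 and 4027 with the higher change in T98G; the cell line cannot be told apart from the run. MIR7-3HG differed by 72.0 ± 2.95 (SE, limma adjusted p = 7.23e-13) and SLC9A3-AS1 by 28.1 ± 7.96 (SE, limma adjusted p = 0.0139, lost without the libraries numbered 1 or 3, with adjusted p over all alternatives from 0.00348 to 0.13). LINC01426 differed by -8.25 ± 3.58 (SE) and passed only without T98G E64FC65 replicate 3 (limma adjusted p = 0.118, 0.029 without it, and 0.029 to 0.494 over all alternatives). In the PANC-1 knockdown run MIR7-3HG was listed at 0 with the combination, as in T98G. SLC9A3-AS1 fell there too, in shCTL cells from 67.0 ± 4.43 to 50 ± 6.56. The histone cluster region held no excess of higher loci in that run. These differences were therefore not seen in both PANC-1 runs and cannot be credited to the cell line.

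Between 26 and 28 Mb of chromosome 6, 29 of 62 loci had the higher combination change in PANC-1 and 2 the lower (46.8% higher, against 22.4%; one-sided Fisher's exact test, adjusted p = 0.0228). Here the largest single difference was that of uc003njn.1 (27782080 to 27782518), by 141, which stood at 70.7 ± 9.72 with the combination in PANC-1 and at 69.9 ± 7.5 in DMSO in T98G (n = 3, limma adjusted p = 3.15e-05). In PANC-1 DMSO both it and uc003nhi.3 were at 0, where a fall like that in T98G was not possible. Next was uc003nhi.3 (26271146 to 26271612), by 109 (limma adjusted p = 0.00305, lost without the libraries numbered 1, with adjusted p over all alternatives from 0.00041 to 0.117), which was uneven in PANC-1 at 39.1 ± 33.9 with the combination and stood at 89.5 ± 5.06 in T98G DMSO (n = 3). The largest differences the other way were -96.8 in uc001rbb.4 and -91.7 in uc021zfj.1 (chromosome 6, 132270469 to 132270491), with limma adjusted p of 1.4e-19 and 3.57e-26. These 2 were already at 96.3 ± 0.919 and 91.8 ± 0.0255 in PANC-1 DMSO (n = 3) and at 0 in T98G DMSO, so the top of the scale fixed the difference and it restates the DMSO values. Of the 14263 calls, the value expected in PANC-1 from the change in T98G lay above 100 for 955 and below 0 for 2043 (21% together). The regional call held in 4 of 8 other settings (adjusted p from 0.00142 to 0.781), and 5572 transcripts differed when only those above 0 in every library were tested. Among these, 9 of 29 loci of the region were higher and 1 lower, and the call was lost (one-sided Fisher's exact test, adjusted p = 0.781).

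**Figure D4:**
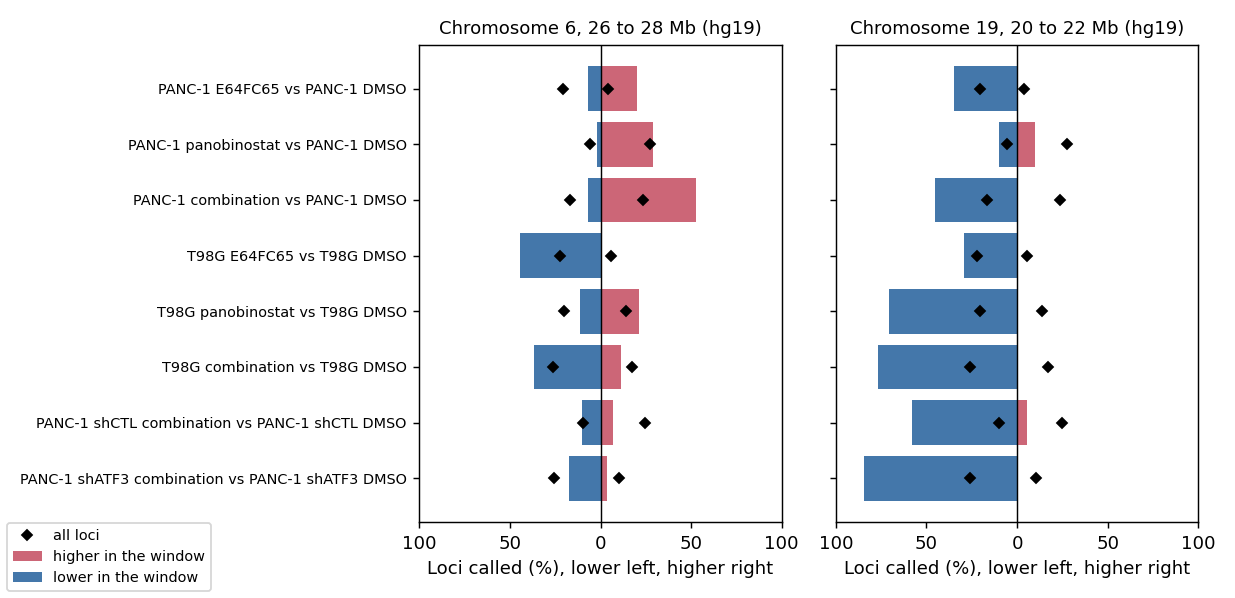
Share of loci (horizontal axis, %) called higher (right) or lower (left) than DMSO in the histone cluster region of chromosome 6 and in the zinc finger region of chromosome 19, per comparison, with diamonds for the share among all loci. With the combination 52.5% of the chromosome 6 loci were higher in PANC-1, and 76.5%, 57.9% and 84.2% of the chromosome 19 loci were lower in T98G, shCTL and shATF3 cells.

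In the knockdown run, the design asks how the loss of ATF3 alters the response to the combination. The files do not pair their identifiers with gene names, so ATF3 was not looked up and the knockdown was not checked here. In shCTL cells the combination raised LINC01426 from 16.1 ± 3.51 to 45.3 ± 4.42 and lowered SLC9A3-AS1 from 67.0 ± 4.43 to 50 ± 6.56 (n = 3, limma adjusted p = 0.000123 and 0.0108). The SLC9A3-AS1 call was lost without the libraries numbered 1 or 2 (adjusted p over all alternatives from 0.00181 to 0.116). MIR7-3HG was listed at 0 in all 12 libraries of the run. In the zinc finger region of chromosome 19, 11 of 19 loci fell and 1 rose (57.9% lower, against 9.91%; one-sided Fisher's exact test, adjusted p = 0.000327, kept in 6 of 8 other settings with adjusted p from 7.27e-05 to 0.764). Of 58742 tested transcripts 13865 changed, 9807 higher and 4058 lower, and 2235 were gained against 76 lost. The largest rises, from 0, were those of uc022cei.1, to 94.2 ± 3.56, and uc021uau.1 (chromosome 17, 57918624 to 57918701), to 93.4 ± 2.55. Falls to 0 were largest in uc002cov.1 (chromosome 16, 2205024 to 2205106) from 93.6 ± 2.99 and uc021puv.1 (chromosome 10, 81526045 to 81526071) from 92.3 ± 0.627 (n = 3, limma adjusted p = 8.43e-09, 1.56e-09, 0.0101 and 0.00946). The last 2 calls were lost without the libraries numbered 1 or 2 and without those numbered 1 or 3 (adjusted p over all alternatives from 4.85e-09 to 0.141 and from 5.41e-11 to 0.0939). Their SEs of 20.9 and 20.3 come from the pooled fit, as the shCTL libraries compared were even. Centring moved the share that was higher from 70.7% to 57.7% (8184 higher, 5999 lower). Grouping shCTL by the treatment label turns every direction of this comparison. By title, its differences correlated with those of the combination in the PANC-1 treatment run at Pearson's r = 0.564 across 56845 transcripts, and the exchanged grouping turns the sign of that correlation. Of the transcripts higher in the treatment run, 4677 were higher and 220 lower in shCTL cells by title. Libraries titled shCTL combination had mean correlations of 0.977, 0.963 and 0.965 with shATF3 combination, and 0.891, 0.885 and 0.884 with shATF3 DMSO. Those titled shCTL DMSO had 0.905, 0.910 and 0.911 with shATF3 combination, and 0.978, 0.976 and 0.975 with shATF3 DMSO. These values argue against the exchanged grouping.

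In shATF3 cells the combination raised LINC01426 from 13.3 ± 1.99 to 35.7 ± 5.37 (n = 3, limma adjusted p = 0.000852). SLC9A3-AS1 fell from 69.1 ± 5.13 to 55.0 ± 3.54 (n = 3, limma adjusted p = 0.0252), a call lost without any one of shATF3 DMSO replicates 1 and 2 and shATF3 combination replicates 1 and 3 (adjusted p from 0.0535 to 0.0894, and from 0.00316 to 0.173 over all alternatives). In the zinc finger region 16 of 19 loci fell and none rose (84.2%, against 25.8%; one-sided Fisher's exact test, adjusted p = 0.000171), which held in all 8 other settings run (adjusted p from 1.16e-07 to 0.0395). The count was 15181, with 4475 higher and 10706 lower, and 1028 transcripts were gained against 402 lost. From 0, uc021uau.1 rose to 93.2 ± 3.72 and uc022azr.1 to 92.4 ± 0.650, the largest rises. Falls to 0 were largest in uc010dee.1 (chromosome 17, 62223438 to 62223517) from 96.9 ± 0.125 and uc002zuf.1 from 91.4 ± 2.97 (n = 3, limma adjusted p = 1.71e-09, 4.24e-09, 0.00919 and 0.00898). The uc010dee.1 call was lost without the libraries numbered 1 or 2 and the uc002zuf.1 call without those numbered 2 or 3 (adjusted p over all alternatives from 2.15e-10 to 0.123 and from 9.18e-06 to 0.144). Their SEs of 21.1 and 19.8 come from the pooled fit, as the shATF3 libraries compared were even. Centring turned the balance from 29.5% to 63.1% higher (9740 higher, 5685 lower). Calls of the PANC-1 treatment run recurred. With the combination, 4677 transcripts were higher both in that run and in shCTL cells (1495 for independent lists) and 1918 lower in both (452.8). For shATF3 cells the numbers were 2756 (688.9) and 3199 (1195). Of those higher in the treatment run, 220 were lower in shCTL and 779 in shATF3 cells. Of those lower in that run, 233 and 92 were higher.

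Between shATF3 and shCTL cells in DMSO, LINC01426 and SLC9A3-AS1 did not differ past the threshold (limma adjusted p = 0.817 and 0.928). Both passed when shCTL was grouped by the treatment label (adjusted p over all alternatives from 6.97e-05 to 1 and from 0.00608 to 1). By title that grouping sets shATF3 DMSO against shCTL combination libraries, so its calls hold the drug effect. Highest above shCTL were uc011kez.1 (chromosome 7, 73149399 to 73150330), at 67.9 ± 14.3 in shATF3 and 0 in shCTL, and uc010igy.1 (chromosome 4, 56686237 to 56703430), at 58.9 ± 14.8 and 0. Lower in shATF3 were uc003iii.3 (chromosome 4, 141309607 to 141348815), at 61.0 ± 2.73 and 73.0 ± 4.85, and uc002erc.3 (chromosome 16, 67143866 to 67182442), at 84.5 ± 1.1 and 92.4 ± 0.815 (n = 3, limma adjusted p = 0.00463, 0.00228, 0.0457 and 0.000431). For uc010igy.1, with an SE of 5.63, the p-value understates the spread of the shATF3 libraries, as a group at 0 adds none. The calls on uc011kez.1 and uc002erc.3 were lost without the libraries numbered 1 or 2 (adjusted p over all alternatives from 0.000534 to 0.414 and from 7.2e-07 to 0.222). The call on uc003iii.3 was lost without any one of 10 of the 12 libraries of the run, all but shATF3 DMSO replicate 3 and shCTL DMSO replicate 2 (adjusted p from 0.0646 to 0.179, and from 1.32e-05 to 0.443 over all alternatives). In all 408 transcripts differed, 349 higher and 59 lower in shATF3. The count was 3012 without shATF3 DMSO replicate 3, and 107 and 100 without replicates 1 and 2 of that group. It was 233, 229 and 243 without shATF3 combination replicates 1, 2 and 3, 230 and 203 without shCTL combination replicates 2 and 3, and 260, 188 and 163 without shCTL DMSO replicates 1, 2 and 3.

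Under the combination, shATF3 cells mostly had the lower TIN. The transcripts uc002vsl.2 (chromosome 2, 232786805 to 232791038) and uc001llu.3 (chromosome 10, 134750621 to 134756089) were listed at 0 in shATF3 and stood at 65.2 ± 10.2 and 47.6 ± 10.8 in shCTL (n = 3, limma adjusted p = 5.69e-05 and 0.000756). Groups at 0 add no spread to the pooled fit. The SEs of 3.89 and 4.14 and these p-values therefore understate the spread of the shCTL libraries. Both calls were lost when shCTL was grouped by the treatment label (adjusted p over all alternatives from 5.85e-06 to 1 and from 2.49e-05 to 1). By title that grouping sets shATF3 combination against shCTL DMSO libraries, so the loss says little about how stable the calls are. The largest rises were those of uc002aya.3 (chromosome 15, 74753606 to 74773633), at 66.4 ± 6.71 against 49.8 ± 3.07, and uc001tqc.1 (chromosome 12, 110478983 to 110486326), at 83.1 ± 2.31 against 67.2 ± 3.82 (n = 3, limma adjusted p = 0.0227 and 0.0465). The first of these was lost without shCTL combination replicate 2 or 3 (adjusted p from 0.067 to 0.0944, and from 0.000927 to 0.339 over all alternatives). The call on uc001tqc.1 was lost without any one of 9 of the 12 libraries, excepting shATF3 DMSO replicate 3 and shCTL DMSO replicates 1 and 2 (adjusted p from 0.0645 to 0.16, and from 0.0204 to 0.319 over all alternatives). In all 1942 transcripts differed, 271 higher and 1671 lower in shATF3, and centring moved the share that was higher from 14.0% to 39.7% (656 higher, 998 lower). The count was 4689 without shCTL combination replicate 1, and 340 and 249 without replicates 2 and 3 of that group. It was 3486 and 1202 without shATF3 DMSO replicates 3 and 2, 1137 and 970 without shATF3 combination replicates 2 and 3, and 1245, 1107 and 1179 without shCTL DMSO replicates 1, 2 and 3.

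The test of whether the knockdown altered the response to the combination called 517 transcripts, 8 with a higher and 509 with a lower response in shATF3 cells. LINC01426 and SLC9A3-AS1 were not among them (limma adjusted p = 0.398 and 0.78), but passed when shCTL was grouped by the treatment label (adjusted p over all alternatives from 1.81e-05 to 0.989 and from 0.00187 to 0.999). By title that grouping adds up the drug effects in shATF3 and shCTL cells, so its calls do not show a knockdown effect. ZNF350-AS1 was not called in any comparison of this run with all libraries. Without shATF3 DMSO replicate 3 and shCTL combination replicate 1 it passed in 4 of the 5: the combination in shCTL and in shATF3 cells, shATF3 against shCTL in DMSO, and the response (limma adjusted p = 0.0361, 0.0276, 0.0241 and 0.0141). Those values are the lowest over all alternatives, and the highest are 0.964, 0.826, 1 and 0.929. The response was lower by the largest amount in uc002vsl.2, by -65.2, and uc011kez.1, by -63.4 (limma adjusted p = 0.001 and 0.0335), where the value expected for uc011kez.1 lay above 100 (as for 42 of the 517, 8.12%), and higher in uc002erc.3, by 7.57 (limma adjusted p = 0.00361). The uc002erc.3 call was lost without the libraries numbered 1 or 2 (adjusted p over all alternatives from 1.03e-06 to 0.395). The call on uc011kez.1 was lost without any one of 10 of the 12 libraries, all but shATF3 DMSO replicate 3 and shCTL combination replicate 1 (adjusted p from 0.0528 to 0.116, and from 7.6e-05 to 0.611 over all alternatives). Centring moved the share that was higher from 1.55% to 24.9% (112 higher, 337 lower), and 28 transcripts were called among those above 0 in every library. The count was 6806 without shATF3 DMSO replicate 3 and 3785 without shCTL combination replicate 1, and 14273 without both. It was 150 and 144 without shATF3 DMSO replicates 1 and 2, 343 without shATF3 combination replicate 3, 67 and 65 without shCTL combination replicates 2 and 3, and 286, 206 and 218 without shCTL DMSO replicates 1, 2 and 3.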

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

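The tests of sequencing depth, of RNA integrity in one E64FC65 library and of the 2 shRNA labels were chosen only after the results they bear on had been seen, as were leaving out single libraries, the arrangements that keep main effects and the counts off the scale.

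The responses to the drugs departed from the sum of the single effects for 3943 transcripts in PANC-1 and 5539 in T98G. In PANC-1 the departures were 91.2 in uc010pgs.2, 81.8 in uc003nui.4, -93.6 in uc022cbk.1, -93.5 in uc021osz.1 and -33.3 in SLC9A3-AS1; for the 4 unnamed transcripts the sum lies off the scale, and for uc022cbk.1 and uc021osz.1 this fixed the departure. In T98G they were 96.4 in uc022bgf.1, 91.7 in uc021ved.1, -94.5 in uc021xjf.1, -70.5 in uc010rpm.2 and -18.2 in LINC01426. Of these, the sum for uc021ved.1 lies below 0, off the scale. Among 100 splits of each run's libraries, the real one alone reached its count (1 of 100 in each line), and the highest other split gave 741 in PANC-1 and 2232 in T98G. Chance can thus be excluded for the PANC-1 count. For T98G this covers only the spread between its libraries, which may be technical. As those splits mix the main effects into the spread, residuals were also permuted with main effects kept, where the highest of the 99 other counts was 0 in PANC-1 and 3 in T98G. The combination response differed between the treatment runs of PANC-1 and T98G for 14263 transcripts, among them uc003njn.1 by 141, uc003nhi.3 by 109, uc001rbb.4 by -96.8, uc021zfj.1 by -91.7, MIR7-3HG by 72.0 and SLC9A3-AS1 by 28.1. For uc001rbb.4 and uc021zfj.1, near the top of the scale in PANC-1 DMSO already, the scale fixed the difference, and it is no sign of another response. For the count of 14263, 2 of 100 splits gave as many calls. The other one (17775) divided the libraries nearly by cell line and points to a structure of the samples. That share is not corrected over the 4 comparisons of effects, so these splits do not exclude chance. With main effects kept, the real arrangement alone reached the count (1 of 100) and the highest other count was 0. That too covers only the spread between libraries, which may be technical in T98G. The combination response differed between shATF3 and shCTL cells for 517 transcripts, among them uc002erc.3 by 7.57, uc002vsl.2 by -65.2 and uc011kez.1 by -63.4. Here 3 of 100 splits reached the count; the highest, 16803, set all DMSO against all combination libraries and points to the treatment as a structure of the samples. With main effects kept, 3 of 100 arrangements of residuals (highest 3637) and 4 of 100 exchanges of the shRNA within treatments (highest 2515) reached it. These shares lie just under 0.05 and are not corrected over the 4 comparisons of effects, and single arrangements gave far larger counts. Chance is therefore not excluded for the knockdown. The count is also unstable, from 6 without the libraries numbered 2 to 14273 without the 2 doubted libraries.

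The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and in each of them 1 of the 10, the real one, gave the count. In PANC-1 the real counts were 9809, 14550, 17979, 6911 and 17409 for E64FC65, panobinostat and the combination against DMSO and the combination against panobinostat and E64FC65, and the highest other splits gave 12, 6, 15, 39 and 23. In T98G the real counts were 10498, 13670, 18519, 5600 and 17134 in that order, and the highest others 12, 6, 4, 24 and 8. In the knockdown run the counts were 13865 and 15181 for the combination in shCTL and shATF3 cells and 408 and 1942 for shATF3 against shCTL in DMSO and in the combination, with 2, 5, 135 and 259 as the highest others.

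Panobinostat raised the number of detected transcripts in PANC-1 by far more than in T98G, 4775 gained against 1422. Deeper panobinostat libraries could give such a rise, and they would also lift transcripts that were thinly covered in DMSO. Of 6130 transcripts with a TIN of 5 to 30 in DMSO replicate 1, 79.7% were higher with panobinostat than in DMSO replicates 2 and 3, against 30.4% with E64FC65 in PANC-1 and 54.1% with panobinostat in T98G. Depth therefore stays open as an explanation, beside a gain of transcription under a histone deacetylase inhibitor, which these values do not separate from it. Pairs of neighbouring silent loci both gained did not pass a permutation test among silent loci: 130 in PANC-1 against a mean of 124 in 1000 permutations (one-sided permutation p = 0.28), and 16 against 11.4 in T98G (p = 0.11).

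Replicate 3 of E64FC65 in PANC-1 had a median TIN of 71.0 against 77.7 and 77.1 in the other replicates, and leaving it out took the combination against panobinostat from 6911 to 10903 calls. A stronger drug response in that library is argued against, since its difference from replicate 1 correlated with the drug effect in replicate 2 at r = -0.0606 across transcripts. Lower RNA integrity could lower most well covered transcripts at once, and 75.4% of those above 50 in replicates 1 and 2 were lower in replicate 3 than in both. That share largely restates the lower median and so does not test RNA integrity, which stays open. The median over mitochondrial transcripts was not lower in replicate 3, at 91.98 against 90.65 and 88.97 in replicates 1 and 2.

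In the knockdown run, shATF3 DMSO replicate 3 lay at a mean distance of 5.56 from the shCTL DMSO libraries and 7.98 from its own group, and shCTL combination replicate 1 at 6.18 from the shATF3 combination libraries and 8.09 from its own. A wrong shRNA label on each could give this. The distance to the other group was 1.07 and 1.1 times the distance among that group's libraries. If both labels were wrong and the knockdown acted alike under both treatments, the 2 departures would be opposite. Their correlation across transcripts was positive, at r = 0.417, which argues against that case. A wrong label on a single library, or on both with unlike knockdown effects under the 2 treatments, stays open. One technical difference shared by the remaining libraries of both groups stays open too. Those libraries list more transcripts above 0 (56897 and 56682 in shATF3 DMSO, 59293 and 59144 in shCTL combination). A rise in TIN there would lower the response in shATF3 cells, the direction of 509 of the 517 calls. Leaving out both libraries took the knockdown comparisons from 408, 1942 and 517 calls to 4936, 8536 and 14273. The real effect of the knockdown stays among the explanations as untested, as ATF3 itself was not looked up.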

How the results depend on the processing

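Leaving out single libraries or the 2 doubted libraries of the knockdown run, one transcript per locus, the arcsine scale, spans of at least 1 kb, leaving out haplotype sequences and all settings of the regional counts were chosen after seeing the data. No filter, the arcsine scale, spans of at least 1 kb and leaving out haplotype sequences kept each of the 18 counts of changed transcripts within 1.5 times. Of the named transcripts, 3222 results under alternatives stayed on the same side of the threshold, 148 fell below it, 13 passed it and 13 reversed. The planned fits with one transcript per gene, the gene lists and their estimated correlation were not run, as identifiers are not paired with gene names. Depth, not used here, limits every count of gained transcripts; where no cause is named below, the cause was not tested.

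Testing only transcripts above 0 in every library, which leaves out gained and lost ones, gave 6875 for panobinostat, 11066 for the combination, 10260 for the combination against E64FC65 and 2341 for the departure from the sum in PANC-1, 1132 for shATF3 against shCTL in the combination, 28 for the knockdown effect on the response and 5572 for the cell line difference. That setting also ended every regional call in the histone cluster region, with fewer loci tested. Those calls are therefore not shown for transcripts covered in every library. Centring gave 4103 for the combination against panobinostat in PANC-1 and 16373 for E64FC65 in T98G. One transcript per locus, with fewer units tested, gave 2239, 3621, 4220, 1479, 4186 and 1013 in PANC-1, 2484, 3051, 4378, 1423, 4100 and 1386 in T98G (E64FC65, panobinostat, combination, combination against panobinostat and against E64FC65, departure from the sum), 3121 and 3250 for the combination in shCTL and shATF3, 68 and 462 for shATF3 against shCTL in DMSO and in the combination, 152 for the knockdown effect on the response and 3652 for the cell line difference.

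Leaving out replicates or libraries gave ranges, in the same order, of 3952 to 10709, 10023 to 17846, 11438 to 24070, 1136 to 10903, 12265 to 20284 and 732 to 5226 in PANC-1, and 5099 to 11193, 7523 to 14538, 11188 to 19859, 1486 to 9057, 10351 to 19602 and 1557 to 9004 in T98G. In the knockdown run they were 5400 to 16496 and 4566 to 20676 for the combination in shCTL and shATF3, 3 to 4936 and 8 to 8536 for shATF3 against shCTL in DMSO and in the combination, and 6 to 14273 for the effect on the response; for the cell line difference the range was 9833 to 16959. The lowest counts came without replicate 2 (replicate 3 in T98G), with 2 libraries per group. The highest came without E64FC65 replicate 3 in PANC-1, without combination replicate 1 in T98G and without the 2 doubted libraries in the knockdown run.

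The replicate numbers did not pair the libraries: 1 of 18 same-numbered pairs in PANC-1, 0 of 18 in T98G and 2 of 18 in the knockdown run deviated together with a correlation above 0.1, and the own number correlated best in 6, 4 and 7 of 18. The replicate block gave 168 and 948 calls for shATF3 against shCTL in DMSO and in the combination and 189 for the effect on the response, and kept the other 15 counts within 1.5 times.

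Grouping shCTL by the treatment characteristic gave 13865 (4058 higher, 9807 lower) for the combination in shCTL, 13547 and 13421 for shATF3 against shCTL in DMSO and in the combination and 20466 for the effect on the response. The correlations between libraries argue against this grouping, which by title sets DMSO against combination libraries when shATF3 is compared with shCTL. In that grouping the combination in shCTL changed uc022cei.1 by -94.22, uc021uau.1 by -93.39, uc002cov.1 by 93.6, uc021puv.1 by 92.3, LINC01426 by -29.18 and SLC9A3-AS1 by 17.02. For shATF3 against shCTL, uc011kez.1 differed by -13.35, LINC01426 by -31.97 and SLC9A3-AS1 by 19.1 in DMSO, and uc002aya.3 by -20.84 and LINC01426 by 19.59 in the combination. The effect on the response was 65.2 in uc002vsl.2, 99.01 in uc011kez.1, 51.55 in LINC01426 and -31.09 in SLC9A3-AS1.

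The median TIN over all transcripts above 0 in a library, which takes in newly gained ones, turned sign for panobinostat in PANC-1 (-0.927), the combination against E64FC65 in T98G (-0.323) and the combination in shCTL (-0.563). At an adjusted p of 0.01 the shared calls with the PANC-1 combination were 1864 lower in T98G, 3112 higher and 910 lower in shCTL and 1815 higher and 1326 lower in shATF3; between the lines, panobinostat shared 530 lower and E64FC65 141 higher and 1699 lower.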

Other observations

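The tests of silent loci by chromosome were chosen after the results had been seen. They take no account of locus length or of neighbouring loci. With panobinostat in PANC-1, 11.5% of transcripts spanning under 1 kb of the genome rose, against 29.9% of those spanning over 100 kb. Whether genomic span or clustering of loci gives the differences between chromosomes was not tested.

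Loci listed at 0 in both lines, called silent here, tended to be gained in both. Of 8968 loci at 0 in DMSO of both lines, panobinostat gained 827 in PANC-1 and 189 in T98G, with 157 in common where independent lists would share 17.4. For the combination the shared number was 167, against 16.3, and for E64FC65 it was 5, against 0.0999. These expectations treat every locus at 0 as equally able to be gained. The odds ratio was 59.4 with panobinostat, 67.3 with the combination and 71.5 with E64FC65, which lowered the number detected. The excess therefore does not by itself show a shared drug response. Silent loci of chromosome 15 were gained less often than those of the other chromosomes together: 6.32% with panobinostat in PANC-1 (Fisher's exact test, adjusted p = 4.15e-08), 1.82% with panobinostat in T98G (adjusted p = 0.0134), 2.79% with the combination in shCTL cells (adjusted p = 0.000282) and 5.13% with it in PANC-1 (adjusted p = 4.62e-07). With the combination in T98G and in shATF3 cells, at 2.48% and 1.36%, the difference did not pass (adjusted p = 0.0539 and 0.059). On chromosome 19 the share in T98G was 8.38% with panobinostat and 8.18% with the combination, above that of the others (adjusted p = 0.000456 and 0.00985), and 10.5% in shCTL cells with the combination (adjusted p = 0.0103). In PANC-1 it was 16.2% with panobinostat and 14.2% with the combination, and in shATF3 cells 5.58%, and none of these passed (Fisher's exact test, adjusted p = 0.291, 0.249 and 0.059). Chromosome 20 was above the others in PANC-1 and T98G with panobinostat and in shCTL cells (20.9%, 8.74% and 12.6%; adjusted p = 0.0345, 0.033 and 0.0103), but did not pass with the combination in PANC-1, T98G and shATF3 cells (14.4%, 6.8% and 7.25%; adjusted p = 0.428, 0.266 and 0.059). Chromosome 12 was so in PANC-1 with panobinostat and in shCTL cells (20.3% and 11.1%; adjusted p = 0.0117 and 0.0103), and chromosome 14 was below them in both (9.45% and 3.7%; adjusted p = 0.0345 and 0.0375). In PANC-1 with the combination, T98G with panobinostat, T98G with the combination and shATF3 cells neither passed (adjusted p = 0.105, 0.223, 0.103 and 0.459 for chromosome 12, and 0.0759, 0.204, 0.164 and 0.236 for chromosome 14). Calls in a single comparison were made on chromosome 7 with panobinostat and on chromosomes 5 and 9 with the combination in PANC-1, and on chromosomes 3, 6 and 8 in shCTL cells (adjusted p = 0.0282, 0.0357, 0.0357, 0.0465, 0.0103 and 0.03).

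MIR7-3HG stood at 72.0 ± 5.52 (SD, n = 3) with the combination in the PANC-1 treatment run and was listed at 0 in all 6 combination libraries of the PANC-1 knockdown run, which used cells of a later passage, other constructs and, by some labels, E64FC26; the difference between the runs was not tested, and a TIN of 0 does not show that the RNA was absent. SLC9A3-AS1 likewise stood at 36.1 ± 7.30 in DMSO in the treatment run and at 67.0 ± 4.43 in shCTL DMSO. The zinc finger region of chromosome 19 had 9 of 20 loci lower and none higher with the combination in the PANC-1 treatment run (45%, against 16.6% of all loci), which did not pass (one-sided Fisher's exact test, adjusted p = 0.379, unadjusted p = 0.00271). In the knockdown run 11 and 16 of 19 loci were lower in shCTL and shATF3 cells, the same direction, and a difference between the runs was not tested. The histone cluster region had 4 loci higher and 6 lower of 58 in shCTL cells (6.9% higher, against 24.6% of all loci) and 2 higher and 10 lower of 58 in shATF3 cells (3.45%, against 10.4%), with no excess of higher loci in this run (adjusted p = 1 for both), against 52.5% higher with the combination in the treatment run.

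Transcripts of the mitochondrial genome, 20 in the tables and 18 or 19 tested, gave few calls. With the combination in PANC-1, 4 of 19 were lower by limma than in DMSO (4 when adjusted over the list alone) and 6 lower than with panobinostat (6 over the list alone). With the combination in shCTL cells 2 of 18 were higher (8 over the list alone), and in DMSO 1 of 18 was higher in shATF3 than in shCTL (10 over the list alone). Both comparisons use the shCTL DMSO libraries, whose median over these transcripts was 85.6 ± 2.56, against 89.5 ± 2.19 in shCTL combination, 90.6 ± 0.837 in shATF3 DMSO and 89.7 ± 0.615 in shATF3 combination (SD, n = 3). Its replicates 1, 2 and 3 were at 85.15, 88.38 and 83.33, where the deposited table of replicate 1 writes its values with fewer digits than the others. With each library centred on its median, 14 of 18 were higher with E64FC65 in T98G, and the 4 and 6 calls in PANC-1 were not made.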
